A study of Drosophila melanogaster with 6 samples.

How the data were processed

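Polyadenylated RNA from whole Drosophila melanogaster testes was sequenced in 3 genotypes, each with 2 libraries of 150 pairs of testes. The control carried the bamGal4 driver alone, and the knockdowns added a hairpin against Pcf11 or against crowded by cid (cbc), per the labels. The libraries were made with a directional kit. Crosses were kept for 3 days at 25 °C and the progeny were then moved to 29 °C. The labels do not say whether the 2 libraries of a genotype came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

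The values analysed were counts of reads per gene as the authors deposited them, without normalization, and for Pcf11 knockdown library 1 counts of reads per splice junction. The submitters' processing notes name Trim Galore, STAR, SAMtools and deepTools and the builds dm6 and BDGP6. Tool versions and the annotation release were not given in the sources used here. Per the layout of the deposited files, the counts were made by the gene counter of STAR, which counts uniquely mapped reads and reports them without regard to strand and for each strand. The sense column was used throughout. Reads counted on the antisense strand made up 3.10% and 3.08% of the stranded counts in the controls, 3.16% in the Pcf11 library, and 3.52% and 3.63% in the cbc libraries. A per-gene count file was analysed for 5 of the 6 libraries. No per-gene counts of Pcf11 knockdown library 1 were analysed here, so it entered no count test.

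Each count file began with 4 totals that name no gene, and these stayed out of library sizes and tests. Reads assigned to no gene on the sense strand made up 1.36% and 1.35% of uniquely mapped reads in the controls and 1.53% in the Pcf11 library. In the cbc libraries they made up 2.62% and 2.86%. They include reads in introns and reads antisense to a gene. Reads assigned to more than 1 gene made up 4.53%, 4.55%, 4.88%, 4.51% and 4.45% in the same order. Unmapped reads made up 23.5% and 28.0% of all reads in the controls, 25.2% in the Pcf11 library, and 30.1% and 27.5% in the cbc libraries. Multimapping reads made up 2.39%, 2.14%, 2.42%, 2.37% and 2.46%. Because only uniquely mapped reads were counted, close gene copies lost reads or exchanged them, and values for such copies are uncertain. Symbols and coordinates came from a BDGP6 annotation in which 17710 of the 17807 gene identifiers were found. Its release may differ from that of the authors.

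Genes with at least 10 counts in at least 2 of the 5 libraries were kept (13960 genes). A quasi-likelihood model of edgeR 4.0.16 with TMM scaling was fitted in R 4.3.3 to the 3 groups together, with the genotype as the only term. This left 2 residual degrees of freedom, to which edgeR added 9.33 prior degrees of freedom, and the common dispersion was 0.00687. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The Pcf11 contrast rests on 1 library, which was assumed to vary like the control and cbc libraries. Levels in CPM, the counts of a gene per 1e6 of the library total, were scaled with TMM factors, and errors are the SD over libraries for CPM and the SE of the fit for log2 fold changes. Intervals are 95% and, like the floor of 3 counts used for genes without reads in a group, cover counting error only. The floor of 3 counts corresponded to between 0.0409 and 0.0476 CPM in the deep libraries and to 0.128 and 0.136 CPM in the cbc libraries.

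Named genes followed a fixed rule: both knocked-down genes, then for each comparison with control the 8 largest rises and the 8 largest falls in log2 fold change among genes past the threshold with a mean of at least 10 CPM and all knockdown libraries on the same side of both controls, then 5 each way for cbc against Pcf11, and then up to 3 members of each gene list by absolute log2 fold change. Gene lists numbered 23 and covered 3' end processing, Integrator, tRNA splicing, stages of the male germ line, Y-linked fertility genes, other cell types in or near the testis, heat shock proteins, apoptosis and DNA damage, antimicrobial peptides, the siRNA pathway, histones and ribosomal proteins. The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The lists held 7 names that matched no symbol of the annotation (Cpsf5, IntS8, Archease, esg, S-Lap6, o-cup and tahi). Such a gene may be counted under another symbol, and S-Lap6 was taken to be another name of loopin-1, which was in the same list and was measured. Lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 22 lists. None of these list tests matched genes by control expression.

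Comparisons that share controls were set beside 20 simulated draws of unchanged groups and beside the overlap of independent lists. Junction reads of Pcf11 knockdown library 1 were summed per gene over junctions that matched an intron of the annotation. Their log2 values were regressed across genes on the log2 CPM of control 1 and the number of introns, and the residuals were compared with log2 fold changes against control 2. A second regression held the log2 CPM of control 1, the log2 number of introns, the log2 exon length and both log2 fold changes. Gene neighbours within 1000 bp were compared by permutation with 100000 resamples. Families examined in the closing section were compared with other genes within strata of control expression, also with 100000 resamples.

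Alternatives were DESeq2 1.42.0, RLE scaling, library totals without scaling, no filter and filterByExpr, the unstranded column, only the compared libraries, the replicate number as a block, a minimum absolute log2 fold change of 1, and each control and cbc library left out in turn. Thinning every library to the smallest total and the comparisons of neighbours within strata of expression were added after the data were seen. The tests were checked on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. For cbc, 48% and 81% of these were recovered and 9 of 13743 unchanged genes were called. For Pcf11, 61% and 74% were recovered and 25 of 13743 were called. In a list test of the simulation the shifted list was found in both comparisons, with 0 of 22 other lists called for cbc and 1 of 22 for Pcf11. The simulation drew genes independently and changed few of them, nearly equally in both directions. It therefore did not check the scaling where most genes change, or the list test where genes are correlated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.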

Results

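The series measured polyadenylated RNA in adult testes after knockdown of 2 factors of 3' end formation, with the bamGal4 driver, which acts as spermatogonia turn into spermatocytes. Pcf11 and cbc, the fly homologue of Clp1, are subunits of cleavage factor II, which takes part in cleavage of the nascent transcript and in termination. The 2 controls had 76132580 and 73600622 reads assigned to genes. Pcf11 knockdown library 2 had 79053532, and the 2 cbc knockdown libraries had 18954932 and 20510200. For Pcf11 knockdown library 1 only splice junction reads were analysed. The library titles followed 2 naming styles, with the controls and Pcf11 library 2 in the first and the cbc libraries and Pcf11 library 1 in the second. Style and depth went with genotype when cbc was compared with control or with Pcf11 library 2, so a batch and the genotype cannot be told apart in those counts. Libraries of a group differed from each other by more than sampling noise, with a chi-square per degree of freedom of 53.5 between the controls and 7.98 between the cbc libraries.

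Each hairpin lowered its target, and the Pcf11 transcript was higher when cbc was knocked down. The cbc gene (FBgn0033842, chromosome 2R from 13483512 to 13485391, minus strand, BDGP6) was at 54.7 ± 3.13 CPM in control (SD, n = 2) and at 3.62 ± 0.595 CPM in cbc knockdown (SD, n = 2), a log2 fold change of -3.92 ± 0.13 (SE, edgeR adjusted p = 3.7e-10). The Pcf11 gene (FBgn0264962, 2R from 14860936 to 14871071, minus strand) was at 52.3 ± 3.39 CPM in control (SD, n = 2) and at 24.2 CPM in the Pcf11 library, a log2 fold change of -1.11 ± 0.11 (edgeR adjusted p = 3.0e-06). In cbc knockdown Pcf11 rose to 99.8 ± 2.69 CPM (SD, n = 2), a log2 fold change of 0.93 ± 0.08 (edgeR adjusted p = 1.1e-06). The cbc gene was at 63.9 CPM in the Pcf11 library and did not pass the test there (log2 fold change 0.22 ± 0.11, edgeR adjusted p = 0.0968). That call was not stable: the value was 0.37 and passed with RLE scaling, was -0.0625 and did not pass with library totals, and passed at 0.23 with only the libraries compared and at 0.22 without cbc library 2. The knockdown acts in part of the germ line while whole testes were sequenced, and a hairpin can add reads to its own target, so these values do not measure the depth of knockdown per cell.

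**Figure D1:**
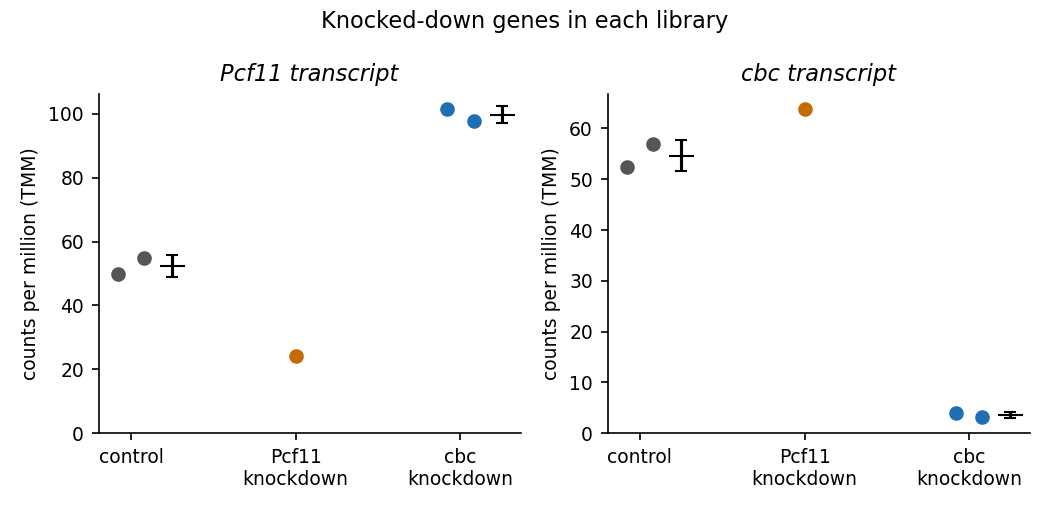
Levels (CPM) of the Pcf11 and cbc transcripts in each of the 5 counted libraries (points), with the mean and SD where a group has 2 libraries (bars). The cbc transcript stood at 3.62 CPM in cbc knockdown against 54.7 CPM in control, and the Pcf11 transcript at 24.2 CPM in Pcf11 knockdown against 52.3 CPM in control.

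The comparison of cbc knockdown with control asks which transcripts changed when this subunit was knocked down. The control carried no hairpin, so effects of a hairpin or its stock cannot be told apart from those of the knockdown. Whole testes were sequenced, so a change in the mix of germ line stages cannot be told apart from regulation within cells. Among genes at low levels in control, prt, which encodes a vesicular transporter, rose from 5.24 ± 0.405 to 819 ± 65.8 CPM (SD, n = 2 each; log2 fold change 7.29 ± 0.12, SE, edgeR adjusted p = 4.6e-12), and CG13613 (3R from 24365554 to 24366349) rose from 1.08 ± 0.179 to 307 ± 5.71 CPM (8.15 ± 0.12). In the other direction the neighbouring genes scpr-A and scpr-B, close relatives whose shared reads are uncertain, fell from 1565 ± 60.3 to 2.70 ± 0.990 CPM and from 1112 ± 80.9 to 2.73 ± 1.15 CPM (log2 fold changes -9.18 ± 0.17 and -8.68 ± 0.18). Of 17 spermatid differentiation genes 15 fell and 1 rose, and of 17 cup and comet genes 12 fell and 5 rose, while 10 of 14 heat shock genes and 5 of 7 fat body genes rose and 0 fell. These lists stood apart from other genes at the preset correlation of camera but not with an estimated correlation (adjusted p = 0.936). The latter test rests on 2 residual degrees of freedom and passed 0 of 22 lists. The estimated correlation was 0.347 for spermatid differentiation, 0.361 for cup and comet and 0.877 for heat shock genes, all above the preset 0.01. The test failed even where the estimate was below 0 (-0.0858 for fat body genes). It therefore cannot decide whether correlation among genes accounts for these results. The list tests also did not match genes by control expression. The median log2 fold change of all genes was 1.85 in the lowest of 10 strata of control expression and -0.38 in the highest.

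The remaining largest rises in cbc knockdown were of lncRNA:CR42836 (9.21 ± 0.24), lncRNA:CR43263 (8.88 ± 0.18), CG13675 (7.91 ± 0.19), the zinc transporter gene Zip89B (6.07 ± 0.13), CG10587 (6.05 ± 0.16) and CG8850 (6.02 ± 0.13). The long noncoding RNAs lncRNA:CR42836 and lncRNA:CR43263 went from 0.0274 and 0.0756 CPM in control to 17.8 and 36.7 CPM. Of the largest falls, CG32457 went from 293 ± 30.9 to 0.108 ± 0.0885 CPM (SD, n = 2 each; -11.35 ± 0.21), Vajk4 from 47.1 to 0.0880 CPM (-9.02 ± 0.22), and 3 genes that lie between 773547 and 779655 on 2L also fell: CG12506 (-9.11 ± 0.14), CG13947 (-9.33 ± 0.20) and CG13946. Only 1 read of CG13946 and 2 reads of CG42870 were left in the cbc libraries, which put CG13946 1566-fold lower (95% interval 281 to 61856) and CG42870 1336-fold lower (95% interval 370 to 11035). Single libraries moved some of these sizes by more than 1.5 times: CG32457 was at -10.72 without cbc library 1 and -12.58 without cbc library 2, CG13947 at -10.35 and -8.69, and lncRNA:CR42836 at 10.05 without control 2. The fitted values of CG13946 (-10.46) and CG42870 (-10.31) were -9.58 and -14.73 without cbc library 1 and -13.95 and -9.29 without cbc library 2, and with so few reads they depend on the prior count. Of 13960 genes tested, 10344 passed, 5074 higher and 5270 lower, and 2657 and 2272 of these differed by at least 2-fold.

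Of 17 measured spermatid differentiation genes, 1 rose and 15 fell in cbc knockdown (16 adjusted over the list alone). The sperm tail genes Mst84Dc (-3.01 ± 0.08), Mst84Dd (-2.44 ± 0.10) and Mst84Db (-1.91 ± 0.10), which are close copies, changed most. The list was lower than other genes (camera adjusted p = 7.0e-06, and adjusted p = 0.936 with an estimated correlation). Of 17 cup and comet genes, which are transcribed after meiosis, 5 rose and 12 fell (17 adjusted over the list alone). The most changed were sowi (-1.98 ± 0.09), boly (-1.92 ± 0.09) and t-cup (-1.67 ± 0.16) (camera adjusted p = 0.00647, and adjusted p = 0.936 with an estimated correlation). Sperm chromatin genes moved both ways, with 2 of 9 higher and 7 lower (9 adjusted over the list alone). Tpl94D, a transition protein gene, rose by 2.75 ± 0.08, and the protamine gene ProtA and tHMG2 fell by 1.54 ± 0.08 and 1.30 ± 0.08 (list adjusted p = 0.382). Of 8 sperm leucylaminopeptidase genes 2 rose and 2 fell (2 adjusted over the list alone), and S-Lap2 changed most (-2.95 ± 0.09, list adjusted p = 0.495). The calls of S-Lap1 (0.25) and loopin-1 (0.23) as higher were not stable, and neither passed without the filter on low counts (0.18 and 0.16).

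Earlier germ line lists did not stand apart from other genes in cbc knockdown. Of 11 spermatogonial genes 4 rose and 5 fell (9 adjusted over the list alone, camera adjusted p = 0.961). Their median was -0.15 while camera pointed up, with aub (-1.56 ± 0.12) and nanos (-1.49 ± 0.21) lower and the differentiation factor mei-P26 (1.24 ± 0.08) higher. Of 15 spermatocyte transcription regulators 1 rose and 8 fell (9 adjusted over the list alone, adjusted p = 0.291), among them aly (-1.35 ± 0.10) and sa (-1.25 ± 0.09). Of 10 meiotic division regulators 6 rose and 1 fell (7 adjusted over the list alone, adjusted p = 0.212), with the Cdc25 phosphatase gene twe (1.41 ± 0.09), polo and CycB (0.95 ± 0.09) in front. Of 11 Y-linked fertility genes 2 rose and 6 fell (8 adjusted over the list alone, adjusted p = 0.701), led by ORY (-1.77 ± 0.21) and kl-5 (-1.28 ± 0.14). Of 17 cleavage and polyadenylation genes 10 rose and 5 fell (15 adjusted over the list alone, adjusted p = 0.588), and after cbc itself Wdr33 (1.43 ± 0.08) and Cpsf160 (1.38 ± 0.09) changed most. Of 13 Integrator genes 3 rose and 5 fell (8 adjusted over the list alone, adjusted p = 0.899), with asun (1.68 ± 0.10) first. The Integrator median was -0.25 while camera pointed up. Of 5 tRNA splicing genes 1 rose and 1 fell (1 adjusted over the list alone, adjusted p = 0.902). Tsen34 rose by 2.05 ± 0.30 in a list whose median was -0.14 and whose test pointed up.

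Among other lists, 10 of 14 heat shock genes rose in cbc knockdown and 0 fell (10 adjusted over the list alone). In front were the near-identical Hsp70Aa (2.85 ± 0.17), Hsp70Ab (2.76 ± 0.16) and Hsp70Bbb (2.71 ± 0.34) (camera adjusted p = 0.0156, and adjusted p = 0.936 with an estimated correlation). The heat shock list did not pass in fry (adjusted p = 0.0588). The spermatid differentiation (0.0312), cup and comet (0.0312) and fat body (0.0256) lists did. Of 7 fat body genes 5 rose and 0 fell (5 adjusted over the list alone, camera adjusted p = 0.0311, and adjusted p = 0.936 with an estimated correlation). Levels stayed low there: Yp1, a yolk protein gene, had 3 reads in control and was 113-fold higher (95% interval 37.6 to 556, for counting error only). Its fitted log2 fold change of 6.66 was 9.73 without control 1 and 5.71 without control 2. Fbp1 reached 7.83 ± 4.79 CPM (SD, n = 2; 3.74 ± 0.37, and 2.94 without cbc library 2), and Lsp1gamma reached 7.81 CPM (2.78 ± 0.17). Genes near silence in control rose in general, with a median of 1.85 in the lowest of 10 strata of control expression. Whether fat body genes stood apart from other genes at equal expression was not tested. Of 91 ribosomal protein genes 3 rose and 57 fell (60 adjusted over the list alone), with RpS28-like (-2.80 ± 0.14) and RpS28a (-2.41 ± 0.17) lowest. Their median was -0.34, while all genes in strata 9 and 10, the highest of control expression, had medians of -0.22 and -0.38. Whether ribosomal protein genes were lower than other genes at equal expression was not tested. Their list passed (camera adjusted p = 0.0157, and adjusted p = 0.936 with an estimated correlation), but not without cbc library 2 (adjusted p = 0.0824) or with library totals (adjusted p = 0.0694). Over 8 alternatives its adjusted p ranged from 4.6e-04 to 0.936. In fry the ribosomal protein list did not pass (adjusted p = 0.125). Of 10 muscle sheath genes 2 rose and 8 fell (10 adjusted over the list alone, adjusted p = 0.305), including Mhc (-1.16 ± 0.13), up (-1.08 ± 0.15) and Act57B (-1.04 ± 0.12). Of 11 cyst and hub cell genes 1 rose and 5 fell (6 adjusted over the list alone, adjusted p = 0.213), led by the hub ligand gene upd1 (-2.55 ± 0.15), Fas3 and hh (-1.62 ± 0.13).

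Of 11 accessory gland genes 5 rose and 0 fell in cbc knockdown (3 adjusted over the list alone, camera adjusted p = 0.588). These genes differed between the controls. Acp53Ea, at 13.8 ± 9.53 CPM in control (SD, n = 2), had a log2 fold change of 1.12 ± 0.34, which was 2.08 without control 2 and did not pass in DESeq2. Without control 2 the list passed (adjusted p = 5.3e-04), with a range of 5.3e-04 to 0.936 over 8 alternatives. Of 6 ejaculatory duct and bulb genes 2 rose and 2 fell (4 adjusted over the list alone, adjusted p = 0.961), led by Dup99B (2.08 ± 0.29), in a list with a median of -0.0040 and a mean of 0.38. Of 4 haemocyte genes 1 rose and 2 fell (3 adjusted over the list alone, adjusted p = 0.867), with NimC1 at 1.88 ± 0.28 and Hml at -1.22 ± 0.16. Of 10 apoptosis and DNA damage genes 3 rose and 5 fell (8 adjusted over the list alone, adjusted p = 0.882), and the death activator rpr fell by 1.99 ± 0.24. Of 12 antimicrobial peptide and recognition genes 2 rose and 6 fell (8 adjusted over the list alone, adjusted p = 0.899), and CecA1 rose by 4.86 ± 0.19 to 12.4 CPM. Of 5 siRNA pathway genes 0 rose and 3 fell (3 adjusted over the list alone, adjusted p = 0.382), with Dcr-2 at -1.60 ± 0.11 and AGO2 at -0.81 ± 0.08. Of 2 histone genes tested, His2B:CG33868, a member of a repeated family, fell by 1.57 ± 0.29 (1 adjusted over the list alone). With library totals in place of TMM the median of all genes shifted by 0.25 and the calls split into 6374 higher and 3943 lower, so directions of small changes are relative to the scaling.

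The comparison of Pcf11 knockdown with control asks the same of the other subunit, with the same limits. In the Pcf11 library 8 of 10 meiotic division regulators and 12 of 17 cup and comet genes were higher, and 87 of 91 ribosomal protein and 9 of 10 muscle sheath genes were lower. These lists stood apart from other genes at the preset correlation of camera but not with an estimated correlation (adjusted p = 0.669 to 0.707). With 2 residual degrees of freedom the latter test has little power and passed 0 of 22 lists. Genes were not matched by control expression here either. The median log2 fold change of all genes was 0.64 in the lowest of 10 strata, -0.48 in stratum 5 and 0.37 in the highest. The transition protein gene Tpl94D rose from 33.9 ± 0.235 CPM in control (SD, n = 2) to 488 CPM (log2 fold change 3.85 ± 0.09, SE, edgeR adjusted p = 3.2e-10), and bol, which encodes an RNA-binding protein needed for meiotic entry, rose from 752 ± 78.4 CPM (SD, n = 2) to 2032 CPM (1.43 ± 0.11). The largest fall was of CG16772, at 142 ± 31.8 CPM in control (SD, n = 2) and 0.397 CPM in the Pcf11 library (-8.48 ± 0.29, edgeR adjusted p = 2.4e-09). These values rest on 1 Pcf11 library, assumed to vary like the control and cbc libraries, and have no replicate check of their own.

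The largest rises in the Pcf11 library were of lncRNA:CR42836 (9.70 ± 0.25, and 10.53 without control 2), lncRNA:CR43263 (9.56 ± 0.18), CG3081 (5.43 ± 0.16), Zip89B (5.42 ± 0.13), CG14826 (4.96 ± 0.16), the transcription factor gene Sox21b (4.86 ± 0.17), CG10587 (4.75 ± 0.17) and the kinase gene Mos (4.58 ± 0.19). Zip89B went from 0.770 to 33.2 CPM and Sox21b from 0.591 to 17.3 CPM. After CG16772, the largest falls were of CG12506 (-7.82 ± 0.16), CG32457 (-7.49 ± 0.19), CG42827 (-7.12 ± 0.21), CG13946 (-7.07 ± 0.26), CG17917 (-6.96 ± 0.23), CG42870 (-6.76 ± 0.22) and CG13947 (-6.75 ± 0.19). Of 13960 genes tested, 9630 passed in edgeR, 4555 higher and 5075 lower, and 1935 and 2768 of these differed by at least 2-fold.

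Of 10 meiotic division regulators 8 rose and 2 fell in the Pcf11 library (10 adjusted over the list alone), led by twe (1.52 ± 0.11), bol and polo (1.42 ± 0.09). The list was higher than other genes (camera adjusted p = 0.00221, and adjusted p = 0.669 with an estimated correlation). All 8 sperm leucylaminopeptidase genes measured rose (8 adjusted over the list alone). Among them were loopin-1 (1.27 ± 0.11), S-Lap3 (1.21 ± 0.11) and S-Lap4 (1.10 ± 0.12) (camera adjusted p = 9.8e-04, and adjusted p = 0.669 with an estimated correlation). Of 9 sperm chromatin genes 7 rose and 0 fell (7 adjusted over the list alone). After Tpl94D came Mst33A (1.11 ± 0.12) and Prtl99C (0.83 ± 0.09) (camera adjusted p = 0.00132, and adjusted p = 0.669 with an estimated correlation). Of 17 cup and comet genes 12 rose and 0 fell (12 adjusted over the list alone). Their largest changes were in f-cup (1.74 ± 0.10), p-cup (1.45 ± 0.09) and r-cup (1.33 ± 0.09) (camera adjusted p = 0.00219, and adjusted p = 0.695 with an estimated correlation). Of 17 spermatid differentiation genes 8 rose and 3 fell (11 adjusted over the list alone, adjusted p = 0.317), with the mitofusin gene fzo at 1.92 ± 0.13 and Mst84Db at -1.54 ± 0.13. Of 11 Y-linked fertility genes 4 rose and 2 fell (5 adjusted over the list alone, adjusted p = 0.607), with CCY at 0.91 ± 0.23 and ARY at 0.90 ± 0.17.

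Of 91 ribosomal protein genes 1 rose and 87 fell in the Pcf11 library (88 adjusted over the list alone). RpL22 (-1.88 ± 0.16), RpS6 (-1.79 ± 0.14) and RpL3 (-1.63 ± 0.14) were lowest, with a list median of -0.89 (camera adjusted p = 4.8e-13, and adjusted p = 0.707 with an estimated correlation). Of 10 muscle sheath genes 1 rose and 9 fell (10 adjusted over the list alone). The troponin T gene up (-2.30 ± 0.19), the myosin heavy chain gene Mhc (-1.69 ± 0.17) and Act57B (-1.52 ± 0.16) were lowest (camera adjusted p = 0.00918, and adjusted p = 0.669 with an estimated correlation). Of 11 cyst and hub cell genes 0 rose and 5 fell (5 adjusted over the list alone), with hh (-2.73 ± 0.18), Fas3 (-2.68 ± 0.13) and tj (-2.21 ± 0.29) lowest. That list was at the threshold (camera adjusted p = 0.0415, and adjusted p = 0.669 with an estimated correlation) and did not pass without control 2 (adjusted p = 0.0503), cbc library 1 (adjusted p = 0.0515) or cbc library 2 (adjusted p = 0.05). Over 8 alternatives its adjusted p ranged from 0.0215 to 0.669. Of 11 spermatogonial genes 2 rose and 7 fell (9 adjusted over the list alone, adjusted p = 0.593), with zpg (-2.33 ± 0.24), aub (-1.91 ± 0.15) and vas (-1.84 ± 0.20) lowest. Of 15 spermatocyte regulators 2 rose and 9 fell (11 adjusted over the list alone, adjusted p = 0.196), led by wuc (-1.32 ± 0.11) and nht (-1.09 ± 0.12).

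All 13 Integrator genes measured changed in the Pcf11 library, 4 higher and 9 lower (13 adjusted over the list alone, adjusted p = 0.317), led by IntS4 (-1.90 ± 0.20, and -0.42 in the unstranded counts) and IntS9 (-1.60 ± 0.19). Of 17 cleavage and polyadenylation genes 2 rose and 7 fell (9 adjusted over the list alone, adjusted p = 0.585), with Ssu72 (-1.28 ± 0.15) lowest and Wdr33 (1.08 ± 0.09) highest. Of 5 tRNA splicing genes 1 rose and 1 fell (2 adjusted over the list alone, adjusted p = 0.74), and the ligase gene RtcB changed most (-1.32 ± 0.12). Of 5 siRNA pathway genes 1 rose and 3 fell (4 adjusted over the list alone, adjusted p = 0.171), with Dcr-2 at -2.40 ± 0.14 and AGO2 at -1.20 ± 0.10. Of 10 apoptosis and DNA damage genes 2 rose and 7 fell (9 adjusted over the list alone, adjusted p = 0.317), and rpr fell by 3.08 ± 0.29. Of 14 heat shock genes 1 rose and 6 fell (7 adjusted over the list alone, adjusted p = 0.317), with Hsp68 at -1.45 ± 0.13. Of 12 antimicrobial peptide and recognition genes 5 rose and 5 fell (10 adjusted over the list alone, adjusted p = 0.906). AttD had no reads in the Pcf11 library, at least 15.6-fold lower than control against a floor of 3 counts over the group. Of 2 histone genes, His2B:CG33868 fell by 1.77 ± 0.31 (2 adjusted over the list alone).

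Of 7 fat body genes 5 rose and 1 fell in the Pcf11 library (6 adjusted over the list alone, adjusted p = 0.196), with Fbp1 (3.64 ± 0.40) first and Yp1 10.8-fold higher (95% interval 3.00 to 58.4). The fitted log2 fold change of Yp1, 3.28, was 6.34 without control 1 and 2.32 without control 2, and it was 1.58 and did not pass in the unstranded counts. Of 6 ejaculatory duct and bulb genes 0 rose and 3 fell (3 adjusted over the list alone, adjusted p = 0.196), led by EbpIII (-1.80 ± 0.12). Of 4 haemocyte genes 1 rose and 3 fell (4 adjusted over the list alone, adjusted p = 0.341), with Ppn at -1.49 ± 0.14. Of 11 accessory gland genes 0 rose and 1 fell (0 adjusted over the list alone, adjusted p = 0.651), namely Acp26Ab (-1.20 ± 0.34), and the list passed as lower without control 1 (adjusted p = 0.00408, range 0.00408 to 0.919 over 8 alternatives). Scaling by library totals shifted the median of all genes by -0.28 and split the calls into 3280 higher and 6467 lower, while RLE scaling shifted it by 0.15 and gave 5283 higher and 4435 lower.

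**Figure D2:**
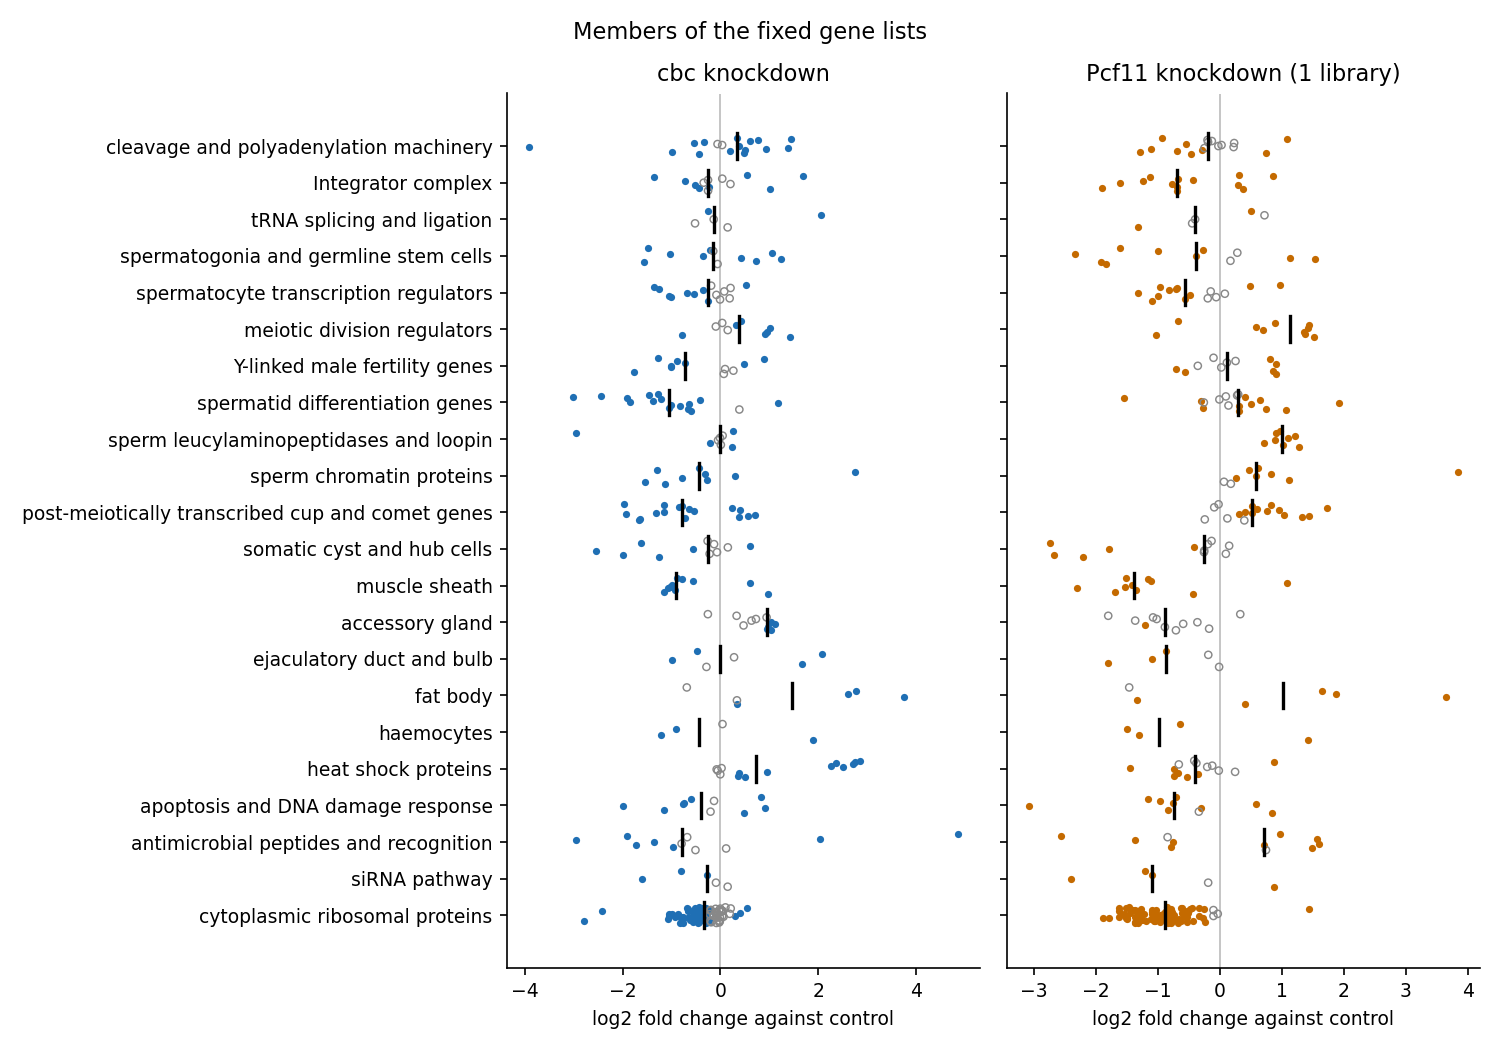
Log2 fold changes against control of the measured members of the gene lists with at least 3 members, for cbc knockdown (2 libraries, left) and Pcf11 knockdown (1 library, right). Filled points passed the edgeR test, open points did not, black bars are medians of the plotted members, and genes with 3 or fewer reads in a group are left out. Ribosomal protein genes lie mostly left of 0 in both panels, with medians of -0.34 and -0.89, and spermatid differentiation genes have medians of -1.05 for cbc, where fzo and gdl lie right of 0, and 0.30 for Pcf11.

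The comparison of the knockdowns with each other asks where knockdown of 2 subunits of the same factor had unequal effects. The target transcripts were not lowered equally, with log2 fold changes of -3.92 for cbc and -1.11 for Pcf11. At the preset correlation of camera, 4 lists of late spermatogenesis genes stood lower and the ribosomal protein and heat shock lists higher in cbc than in Pcf11 knockdown. For each of these 6 lists the result was adjusted p = 0.792 with an estimated correlation, a test that has little power with 2 residual degrees of freedom. All 17 spermatid differentiation genes (17 adjusted over the list alone, camera adjusted p = 1.8e-10) were lower in cbc. So were all 8 leucylaminopeptidase genes (8 adjusted over the list alone, adjusted p = 2.3e-06), all 9 sperm chromatin genes (9 adjusted over the list alone, adjusted p = 1.3e-06) and 16 of 17 cup and comet genes (16 adjusted over the list alone, adjusted p = 1.1e-11). Of 14 heat shock genes 13 were higher in cbc (13 adjusted over the list alone, adjusted p = 7.2e-05), as were 75 of 91 ribosomal protein genes with 4 lower (80 adjusted over the list alone, adjusted p = 6.8e-06). In fry the ribosomal protein list did not pass (adjusted p = 0.0877), while the heat shock list (0.0467) and the 4 late spermatogenesis lists (0.0213 each) did. The accessory gland list did not pass (adjusted p = 0.277) but did without control 1 (adjusted p = 0.00194) or control 2 (adjusted p = 0.00205, range 0.00194 to 0.792 over 8 alternatives).

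The genes that stood highest in cbc relative to Pcf11 knockdown were CG13675 (log2 difference 7.10 ± 0.24), CG13613 (6.92 ± 0.16), prt (5.04 ± 0.14), the cytochrome P450 gene Cyp6a2 (4.84 ± 0.18) and CG18549 (4.76 ± 0.14, and 3.11 in the unstranded counts). Cyp6a2 was at 36.0 ± 0.899 CPM in cbc knockdown (SD, n = 2), 1.25 CPM in the Pcf11 library and 1.07 ± 0.00619 CPM in control (SD, n = 2). Those that stood lowest were CG11905 (-6.81 ± 0.15), CG15711 (-5.34 ± 0.11), CG43610 (-4.66 ± 0.21, and -3.45 in the unstranded counts), scpr-A (-4.59 ± 0.17) and scpr-B (-4.50 ± 0.19). CG11905 moved in opposite directions, from 7.69 ± 0.236 CPM in control (SD, n = 2) to 0.882 ± 0.101 CPM in cbc knockdown (SD, n = 2) and 98.7 CPM in the Pcf11 library. CG15711 fell from 211 to 5.04 CPM in cbc knockdown and was at 205 CPM in the Pcf11 library, where it did not pass the test (-0.04 ± 0.09). In edgeR 10043 genes differed, 5890 higher and 4153 lower in cbc, with 1 Pcf11 library behind them. Library totals shifted the median difference by 0.53 and split the calls into 8514 higher and 2452 lower, and RLE scaling shifted it by -0.14 and gave 5029 and 4633. The excess of higher calls was absent in DESeq2 (4114 higher and 4216 lower) and nearly so with only the libraries compared (4629 and 4517).

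Many genes changed in both knockdowns. In both, 2713 genes were higher and 3076 lower, where independent lists of these sizes would share 1656 and 1916, and simulated unchanged groups against the same controls shared 0.35 and 0.4 on average over 20 draws. A further 593 were higher in cbc and lower in Pcf11 (1845 for independent lists) and 1032 the reverse (1720). Zip89B, CG10587, lncRNA:CR42836 and lncRNA:CR43263 were among the 8 largest rises of both, and CG32457, CG13946, CG42870, CG13947 and CG12506 among the 8 largest falls. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.604 (0.325 for simulated unchanged groups against the same controls) and a Spearman rho of 0.525. The simulated r is a correlation of noise alone, so it is not the part of 0.604 that shared controls explain. Their covariance was 1.20 against 0.0210 in the simulation, a difference of 1.18. With 2 controls, a separate pair could not be given to each knockdown, so the error of the controls entered both comparisons. If counts vary as simulated, this gives a covariance of about 0.0210 of the 1.20 observed. Both knockdowns carried a hairpin that the controls lacked, so a response to any hairpin cannot be told apart from a shared effect of the 2 factors.

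**Figure D3:**
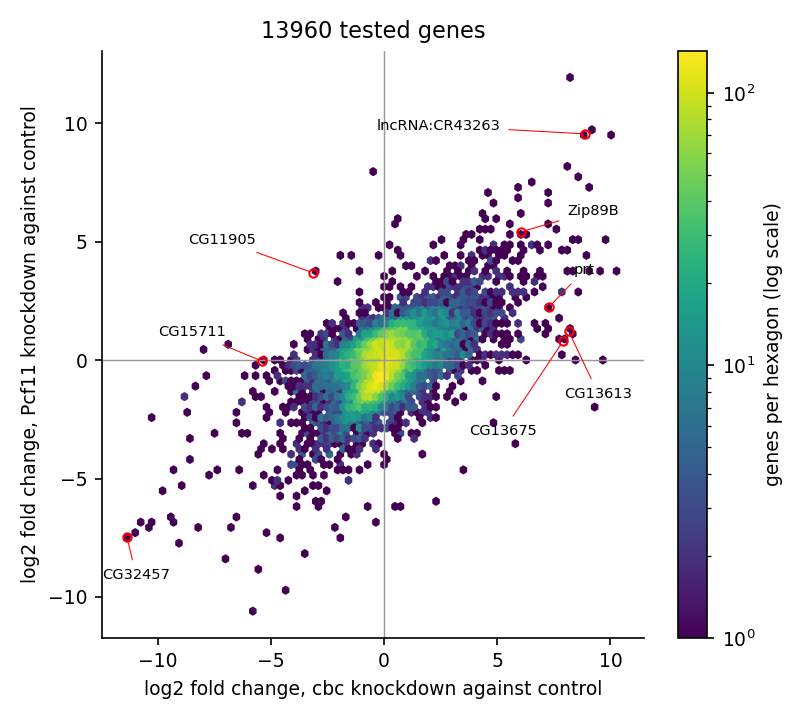
Log2 fold change against control of 13960 genes in cbc knockdown (x axis) and in the Pcf11 knockdown library (y axis), with colour for the number of genes per hexagon on a log scale and red circles for named genes. The cloud rises from lower left to upper right (Pearson r of 0.604 and covariance of 1.20 across genes), and CG11905 lies in the upper left at -3.12 and 3.68. Simulated unchanged groups with shared controls had an r of 0.325, from noise alone, and a covariance of 0.0210.

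Junction reads gave a view of Pcf11 knockdown library 1. It listed 109699 junctions, 101526 of them with at least 1 uniquely mapped read, and 10381354 such reads in all. STAR marked 109383 junctions as annotated, while 47288 (43.1%) matched introns of the annotation used here and carried 94.0% of the reads. The source of that gap is not known. After removal of the part that followed control 1 and the number of introns, the junction reads of 10640 genes correlated across genes with the effect of Pcf11 library 2 against control 2 (Pearson r 0.547, Spearman rho 0.562) and with the cbc effect against control 2 (0.342 and 0.289). A second regression held both effects beside control 1, the log2 number of introns and the log2 exon length. Its coefficient was 0.64 ± 0.011 (SE) for the Pcf11 effect and 0.14 ± 0.012 for the cbc effect. The genes are not independent replicates, so these SEs understate the error.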

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

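The tests of neighbouring genes within strata of expression, of genes under 1 CPM, of thinned libraries, of library batch and of the spread among cell type markers were chosen only after the results were seen.

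The share of reads assigned to no gene on the sense strand and the share of antisense reads were not used in the comparisons of expression. Each share was above both controls in each of the 3 knockdown libraries with gene counts. Reads assigned to no gene made up 1.53% of uniquely mapped reads in the Pcf11 library and 2.62% and 2.86% in the cbc libraries, against 1.36% and 1.35% in the controls. Such reads can lie between genes, in introns or antisense to a gene, so the 2 shares overlap. Antisense reads made up 3.16% of stranded counts in the Pcf11 library and 3.52% and 3.63% in the cbc libraries, against 3.10% and 3.08%. They outnumbered the reads assigned to no gene in every counted library (2434543 against 1101082 in control 1). Part of them therefore also fell on the sense strand of an overlapping gene, and this share does not measure antisense transcription alone. With 2 libraries against 2, a permutation test cannot give a p below 0.33, so these shares were not tested.

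Of 2477 tested genes under 1 CPM in control, a set that the count filter fills in part with genes that rose in a knockdown, 873 (656 of them protein-coding) were called at least 4-fold higher in cbc knockdown and 333 in the Pcf11 library. Counting on the wrong strand is argued against, as the median antisense share over the 873 genes was 3.70%. After every library was thinned to the smallest total, 91.4% of the 873 genes were still called. For the Pcf11 library, which was not shallower than the controls, 72.7% of the 333 were. The smallest total was that of cbc library 1 (18954932 reads, against 20510200 in cbc library 2), so thinning hardly touched the cbc reads. It shows that most of the 873 calls did not need deeper controls. It cannot decide what the low depth of the cbc libraries added. Reads running past the 3' end of an upstream gene may contribute, since among genes under 1 CPM the 248 that start within 1000 bp downstream of an expressed gene had higher log2 fold changes than 157 head-to-head genes, with a difference of medians within 5 strata of control expression of 0.63 for cbc (permutation p = 8.2e-04) and 0.43 for Pcf11 (permutation p = 0.0113). The test over genes of all expression levels within strata gave a difference of 0.12 for Pcf11 (permutation p = 0.00475) and -0.0124 for cbc (permutation p = 0.778). The prediction written before that test was therefore not met for cbc. Without strata, as first planned, the difference was 0.16 for Pcf11 (permutation p = 4.0e-05) and -0.07, the opposite direction, for cbc (permutation p = 0.017). Only 248 of the 1949 downstream genes in these tests lay under 1 CPM, so they say little about near-silent genes. Batch stays open for cbc, as it cannot be told apart from genotype there.

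The cbc and Pcf11 effects differed at 10043 genes, and the titles place the cbc libraries with Pcf11 library 1 and apart from Pcf11 library 2. If a batch that follows the titles were the whole cause, junction reads of Pcf11 library 1 would follow the cbc effect. They followed the Pcf11 effect of library 2 more, by 0.49 in the regression coefficient (0.53 with at least 10 junction reads per gene and 0.67 with the controls exchanged), which argues against batch as the whole cause. Batch as part of the cause and a true difference between the factors stay open. Unequal knockdown stays open too, as the targets had log2 fold changes of -3.92 (cbc) and -1.11 (Pcf11). Those values do not measure the depth of knockdown per cell.

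Of the muscle sheath and the cyst and hub markers, 9 and 5 fell in the Pcf11 library and 8 and 5 in cbc knockdown, with muscle medians of -1.38 in Pcf11 and -0.91 in cbc. A lower share of all other cell types would lower these markers alike. The cyst and hub markers instead moved apart, with an interquartile range of log2 fold changes of 1.84 in Pcf11 and 1.34 in cbc, and zfh1, eya, Socs36E and puc changed by less than 0.3 in both at 10 CPM or more while hh and Fas3 fell by 1.62 or more. The hub ligand gene upd1 changed by less than 0.3 in the Pcf11 library but by -2.55 in cbc knockdown. A lower share of hub cells would lower upd1 too, but its Pcf11 value rests on 1 library. A lower share of muscle or of hub cells alone, and regulation within those cells, may each contribute and were not tested.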

How the results depend on the processing

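The tests of thinned libraries and of neighbouring genes within strata of expression were chosen only after the data were seen. The counts of changed genes stayed within 1.5 times of 10344 (cbc), 9630 (Pcf11) and 10043 (cbc against Pcf11) under other tools, scalings, filters, strand and thinning. DESeq2 called 9238, 8431 and 8330 and thinned libraries gave 9818, 8521 and 9280. Leaving out 1 library at a time gave 9445 to 9935, 8982 to 9952 and 9563 to 10143, with the lone library of a group assumed to vary like the others. A minimum absolute log2 fold change of 1 left 4929, 4703 and 4899, by its construction. In the unstranded counts 51, 41 and 38 genes were called in the opposite direction, and with library totals 74 were for cbc against Pcf11. The replicate number as a block gave 10264, 9187 and 9651 genes and 5, 6 and 7 lists (cyst and hub cells in Pcf11 at adjusted p = 0.0764, accessory gland in the difference at 0.0161), but same-numbered libraries did not deviate together (r = -0.03 over all genes and -0.11 at 10 CPM or more, with only 2 pairs), so the numbers were not taken to pair samples.

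Of the lists, 5, 7 and 6 of 22 passed with the preset correlation and 0, 0 and 0 with an estimated correlation, while fry, which does not compare with other genes, called 7, 13 and 9. The estimated correlation rests on 2 residual degrees of freedom, so its counts of 0 do not show that correlation among genes removes the results. Genes higher in both knockdowns numbered 1652 at 10 CPM or more and 1091 with at least 2-fold change, and genes lower in both 1878 and 982, by construction of fewer genes tested or a stricter threshold. Genes downstream of another gene, compared with other genes for cbc, had differences of -0.06 (permutation p = 0.0628), -0.0709 at 5000 bp (p = 0.00219) and 0.057 within 10 strata of expression (p = 0.0821). Compared with head-to-head genes they had -0.07 (permutation p = 0.017), -0.0551 at 500 bp (p = 0.0828), -0.0124 within 10 strata (p = 0.778) and 0.63 for genes under 1 CPM within 5 strata (p = 8.2e-04). For Pcf11 the differences of 0.10 (permutation p = 0.004) and 0.16 (p = 4.0e-05) were 0.12 (p = 0.00171) and 0.16 (p = 2.0e-05) at 500 bp and became 0.0202 (permutation p = 0.517) and 0.0654 (p = 0.138) at 5000 bp. The cause was not tested.

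Of 176 values of named genes, 168 kept their direction and side of the threshold in DESeq2, 174 with RLE, 172 with library totals, 172 without the filter and 172 in unstranded counts. Reversed were cbc in the Pcf11 library (0.22, and -0.0625 with library totals), Tsen54 in cbc (-0.25, and 0.00030 with library totals) and IntS12 in cbc (-1.35, and 0.20 in unstranded counts). The cause was not tested. The 4-fold lower depth of the cbc libraries limits genes near the floor of 3 counts, at 0.128 and 0.136 CPM there.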

Other observations

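The tests of gene families were chosen only after the results were seen, and those of antisense reads were chosen before. The families were thus picked and tested on the same values, so their p-values are descriptive and give no independent support. Their adjustment covers the 9 families chosen and not others that were looked over.

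The libraries held polyadenylated RNA, so counts at small nuclear RNA genes need not measure the mature RNAs. Which transcripts gave these counts was not tested. Small nuclear RNA genes, most of whose products act in splicing (snRNA:7SKa does not), had higher counts in both knockdowns. Of 17 tested, 17 rose in cbc knockdown and 14 in the Pcf11 library, with medians of 2.79 and 3.04. Compared with other genes at equal control expression, they were higher by 1.75 in cbc (permutation p = 0.00156, adjusted p = 0.0105 over 27 tests) and 2.75 in Pcf11 (p = 1.0e-05, the smallest these resamples can give, adjusted p = 2.7e-04). snRNA:U11 rose from 1.36 ± 0.0804 CPM in control (SD, n = 2) to 19.1 ± 0.124 CPM in cbc knockdown (SD, n = 2) and 20.4 CPM in the Pcf11 library, and snRNA:U12 by log2 fold changes of 3.66 and 3.61. Other members are near-identical copies, whose values are uncertain. In this and the receptor families only members that passed the count filter were tested, some of them only through reads in a knockdown, so the shares that rose are partly set by the filter.

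Ionotropic receptor genes, known from chemosensory neurons, rose in 34 of 40 tested cases in cbc knockdown with 1 lower, with a median of 2.50 and a difference of 1.15 from other genes at equal expression (permutation p = 0.00117, adjusted p = 0.0105). Ir51a rose from 0.131 to 8.68 CPM (6.03 ± 0.25) and Ir85a from 5.92 to 39.8 CPM (2.75 ± 0.12). In the Pcf11 library 22 rose and 2 fell, which did not stand apart from other genes (adjusted p = 0.135), and the difference between the knockdowns did not pass (adjusted p = 0.0948). Odorant receptor (24 of 28 higher in cbc, adjusted p = 0.438), gustatory receptor (24 of 32, adjusted p = 0.0948) and nicotinic receptor genes (8 of 9, adjusted p = 0.322) did not stand apart at equal expression. Of 71 mitochondrial ribosomal protein genes 13 rose and 42 fell in cbc knockdown (difference -0.33, adjusted p = 0.0459), and 9 rose and 36 fell in Pcf11 (difference 0.04, adjusted p = 0.818). The knockdowns differed by -0.42 (adjusted p = 0.0105). Of 79 respiratory chain and ATP synthase genes 19 rose and 33 fell in Pcf11 (difference -0.33, adjusted p = 0.0359), and 5 rose and 55 fell in cbc knockdown (difference -0.20, adjusted p = 0.135). The knockdowns were not shown to differ there (adjusted p = 0.9).

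Of genes that end within 1000 bp of an expressed gene on the opposite strand, reads running past the end of that gene would raise antisense counts. The median log2 change of antisense reads over 603 such genes exceeded that over 869 head-to-head genes by 0.0805 in cbc knockdown (permutation p = 0.223) and 0.0988 in the Pcf11 library (permutation p = 0.0883, adjusted p = 0.177). Neither difference passed, so the prediction written before the test was not met. Both differences were above 0, and a difference that does not pass cannot exclude such reads, so the hypothesis of reads past facing genes stays open here.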
